A study of Arabidopsis thaliana with 8 samples.

How the data were processed

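Roots of Arabidopsis thaliana plants were profiled on 8 Affymetrix ATH1 arrays. Per the labels' protocols, plants spent 10 days on agar with control medium and a further 10 h on fresh control medium or on medium without phosphate (Pi-free). RNA was purified on columns, copied into biotin-labelled RNA and fragmented, per the labels' protocols. The plants were either the wild type Col-0 or the mutant per1, which gave 4 groups of 2 arrays. The labels call the 2 arrays of each group biological replicates.

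The deposited values are linear probeset signal intensities, 1 column per array. The software that summarised probes into probesets, its background step and its scaling target are not given in the sources used here. The 2% trimmed mean was 500 on each array, so the arrays had been scaled to a common level before deposit. The files carry no detection calls. Array medians lay between 186 and 197.1, and the largest signal of the bacterial control probesets whose transcripts were not spiked in was 19.9 to 41.3 per array. Between 14.2% and 15.9% of probesets lay at or under a signal of 16 on each array. The number of arrays limits the precision of each value.

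Of 22810 probesets, 64 controls were left out and 22746 were tested. The platform annotation gave 1 gene for 13513 probesets, several genes for 503 and none for 8730, and only probesets with 1 gene were named. Of the 13513, 13436 were matched through gene identifiers to a locus of the TAIR10.1 annotation, which gave the current symbols of 13286 distinct loci. The remaining probesets are unnamed here, and many well-known genes are among those without a named probeset. UBP14, known from the literature as the gene mutated in per1, and the iron genes IRT1, FRO2 and FER1 were not analysed here for that reason. No start or end coordinates were used. Chromosomes came from the annotation, and loci were ordered along them by their locus identifiers.

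Signals were transformed as log2(signal + 16). All changes are on that scale, which understates the change of low signals. No further normalization was added, since the array medians were close to each other. Each probeset was fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 8 arrays, 4 residual degrees of freedom, and moderated variances with an intensity trend. The SE of each change comes from these moderated variances, shared by the 4 groups. It can therefore be smaller than the spread between the replicate numbers of a gene implies. Probesets with a Benjamini-Hochberg adjusted p under 0.05 were called. The same fit gave 7 comparisons: the Pi response in each genotype, the genotype difference in each medium, their interaction, and both effects averaged over the other factor. On data simulated for the Col-0 Pi response over 22746 probesets, with 200 of them changed in each of 20 runs, the test recovered 92% of probesets changed by 1 on the log2 scale and 100% of those changed by 2. Of all calls in those runs, 6.6% were false. The changed probesets were drawn from those with a mean log2 value above the median of all probesets. The noise was normal, independent between probesets and of equal variance in all groups. Recovery at lower signals, with unequal spreads or with fewer changed probesets was not tested. A list of 15 probesets shifted by -0.5 on the log2 scale passed camera at an unadjusted p under 0.05 in 20 of 20 simulated lists for the same comparison. The list members were drawn from the same upper part of the signals and were not correlated with each other.

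Genes were named by a rule fixed before the data were examined. For the first 4 comparisons, up to 10 higher and 10 lower genes with the largest changes were taken among probesets that were called, had both arrays of one group beyond both of the other, had a mean log2 value above the median of all probesets, and matched 1 gene. Where fewer than 5 qualified in a direction, the 5 with the smallest p that met the other conditions were taken and are given as not past the test where they were not. For the interaction the 10 genes with the smallest p that met the last 2 conditions were taken. For the averaged comparisons the rule took 5 genes in each direction, with the groups required to be separate within each stratum of the other factor. Members of a list are given by their p in that comparison. Unnamed probesets were chosen outside this rule, after their values were seen.

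Of 24 gene lists fixed before the data were examined, 8 had at least 3 named loci on the array and were tested. Only the named members entered these tests: 4 of 25 root hair genes, 3 of 17 green shoot tissue markers, 5 of 25 proteasome subunits and 4 of 25 iron deficiency genes. The same held for 4 of 25 phosphate transport genes, 6 of 13 auxin genes, 3 of 10 reference genes and 20 of 30 class III peroxidases. Because so few loci were named, a further 21 lists were added once the annotation had been read and before any expression comparison was made. Lists were tested with camera at a preset correlation of 0.01 between genes, taking for each locus the probeset with the highest mean, and were adjusted within a comparison over the 8 fixed lists, with the 21 added lists adjusted on their own. Camera with an estimated correlation and fry were run beside it. Across 203 list tests, camera with the preset correlation gave 21 calls and camera with an estimated correlation gave 0, with 8 tests at an unadjusted p under 0.05. No list call therefore held with an estimated correlation. In that setting camera also uses the 4 residual degrees of freedom of the fit, which by itself raises p. The 5 proteasome subunit genes in control medium had an estimated correlation of -0.04, below the preset one. Their unadjusted p from camera still rose from 0.0073 to 0.052. The loss of calls is thus not a measure of correlation between genes alone. Probesets whose identifier ends in _s_at or _x_at can detect more than 1 transcript.

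The spiked hybridization controls differed by replicate number. The signal of the 3' BioD probeset was 3072.7 to 3603.9 on the arrays numbered 2 and 2556.1 to 2723.5 on those numbered 1. Changes within each replicate number are therefore given beside the leading genes. Alternatives changed the normalization, a filter on low signals, the pseudocount, the variance model, the groups in the fit, the threshold and the arrays included, and added the replicate number to the model.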

Results

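RNA from Arabidopsis roots was measured on 8 arrays in 4 groups of 2: Col-0 in control medium, Col-0 after 10 h in Pi-free medium, per1 in control medium and per1 after 10 h in Pi-free medium. Col-0 is the wild type, and per1 is a mutant described in the literature as lacking the lengthening of root hairs that Pi deficiency brings about. The series addresses early transcriptional changes after Pi withdrawal. Spearman correlations across probesets between the 2 arrays of a group were 0.975 for Col-0 in Pi-free medium, 0.978 for per1 in control medium, 0.981 for Col-0 in control medium and 0.982 for per1 in Pi-free medium. The Pi-free Col-0 array of replicate 2 had the lowest mean correlation with the other arrays, 0.9725.

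The Pi response of the wild type was the first comparison. In Col-0 roots, 10 h without Pi raised a small set of transcripts. AT4G38410, a member of the dehydrin family, rose most among the named genes, from a signal of 392 ± 41.6 (SD, n = 2) to 2170 ± 444 (SD, n = 2). Its change was 2.41 ± 0.16 on the log2 scale (SE), with changes of 2.1 and 2.72 within replicate numbers 1 and 2. AT2G32190, which encodes a small cysteine-rich transmembrane-module protein, rose by 1.38 ± 0.17, from 140 ± 5.02 to 392 ± 43.1. AT2G46600, encoding the calcium-binding protein KIC, rose by 1.01 ± 0.11, and the beta-glucosidase gene BGLU25 rose by 0.96 ± 0.11. The adjusted p from limma was 0.00052 for AT4G38410, 0.025 for AT2G46600 and BGLU25, and 0.032 for AT2G32190. No named gene passed the test as lower. The 5 lower genes with the smallest p included ETFALPHA, the alpha subunit of the mitochondrial electron transfer flavoprotein, at -0.91 ± 0.14 with an adjusted p of 0.072, and the class III peroxidase gene PRX69 at -0.88 ± 0.15 with an adjusted p of 0.10. With the replicate number in the model their adjusted p were 0.047 and 0.055. A pair of unnamed probesets, picked outside the naming rule after their values were seen and called A and B here, rose by 3.92 ± 0.14 and 2.30 ± 0.16, with adjusted p of 2.9e-06 and 0.00076. In the 8 fits without 1 array, AT4G38410 passed in 8, and AT2G46600, BGLU25 and AT2G32190 passed in 0, with limma adjusted p of up to 0.35 over all alternatives.

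Among gene groups in Col-0, 14 other phosphate-responsive loci, a list added after the annotation was read, had a median change of 0.34, with 14 of 14 estimates above 0. The list passed camera with an adjusted p of 0.0018, and had an adjusted p of 0.96 with an estimated correlation. None of its members passed over all probesets. Its members with the smallest p were AT2G04460 at 1.11 ± 0.35, VTC4, an enzyme of ascorbate synthesis, at 0.41 ± 0.14 and AT5G20790 at 0.60 ± 0.24. Of the 8 lists fixed beforehand, 0 passed camera in Col-0. Of 20 class III peroxidase genes, 0 were called over all probesets, and adjusted over the list alone 1 rose and 4 fell. The list's median was 0.09, while its mean was -0.05 and its test pointed down, with an adjusted p of 0.76. The 4 measured genes of phosphate transport and its regulators had a median of -0.07, with an adjusted p of 0.76 for the list. The 29 genes fixed as induced by Pi starvation were not analysed here, because 0 of them had a named probeset. Of the 14 probesets called in Col-0, 4 had a single named gene and 10 did not. In total 13 probesets were higher and 1 was lower in Pi-free medium. The count was 3 to 4 whichever of the 8 arrays was left out.

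In per1 roots, the same treatment gave 1 call, the unnamed probeset B, which rose by 2.29 ± 0.16 with an adjusted p from limma of 0.0024. No named gene passed the test. The named genes with the smallest p were lower in Pi-free medium and included AT2G30930 at -0.68 ± 0.11, with an adjusted p of 0.30, and AT1G33700 at -0.68 ± 0.12, with an adjusted p of 0.41. The higher named gene with the smallest p was AT5G19090 at 0.66 ± 0.13, with an adjusted p of 0.51. The count was 0 without the Pi-free per1 array of replicate 2, with 794 probesets at an unadjusted p under 0.05, and 2 without either Col-0 control array. With all arrays, 1016 probesets in per1 and 1747 in Col-0 had an unadjusted p under 0.05, where 1137 would arise by chance. The fit pools 1 variance per probeset over all groups. The median within-group SD was 0.178 in Pi-free Col-0 and 0.125 in Pi-free per1, so the unequal spread also bears on these counts.

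The 4 measured of the 25 genes in the root hair list fixed beforehand shifted down as a list in per1 after Pi withdrawal, with a median of -0.33. PRX44, a root hair peroxidase gene, stood at -0.65 ± 0.13, with a signal of 4630 ± 621 in control medium and 2930 ± 29 in Pi-free medium. The expansin genes EXPA18 and EXPA7, whose products loosen cell walls, stood at -0.33 ± 0.11 and -0.33 ± 0.15. Camera gave an adjusted p of 0.00037 for this list and an adjusted p of 0.27 with an estimated correlation. Over all probesets 0 of the 4 were called, and adjusted over the list alone 2 fell. A list of 16 root hair extensins and further root hair genes, which holds these 4, had a median of -0.11 and an adjusted p of 0.030, or an adjusted p of 0.71 with an estimated correlation. Without the 4 shared genes its median was -0.02, with an unadjusted p of 0.27. The 9 xyloglucan hydrolase genes, with a median of -0.10, and the 69 plastid-encoded genes, with a median of 0.24, also passed camera, with adjusted p of 0.030 and 1.4e-05. With an estimated correlation the adjusted p was 0.71 for both. In the 8 fits without 1 array the fixed root hair list passed in 8, the plastid list in 7, and the longer root hair and xyloglucan hydrolase lists in 5.

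**Figure D1:**
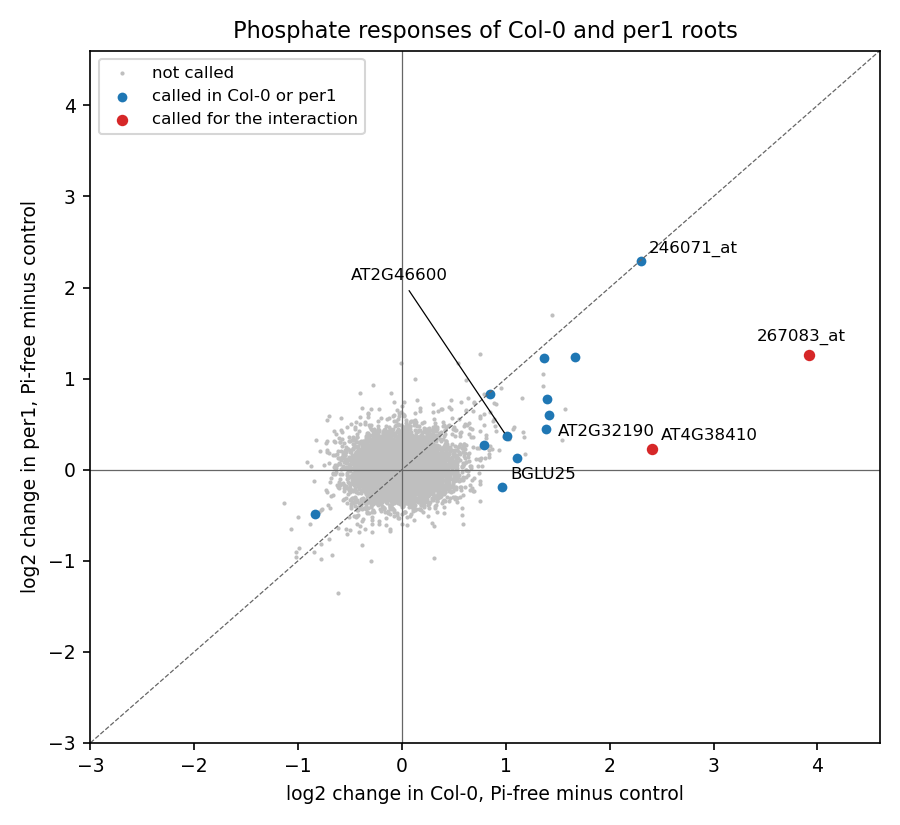
Each point is a probeset with a mean signal above the median. The x axis is its log2 change in Col-0 and the y axis its log2 change in per1, Pi-free minus control, with 2 arrays per group; the dashed line marks equal changes. The unnamed probeset B, labelled with its array identifier, has values of 2.30 and 2.29, and AT4G38410 has values of 2.41 and 0.23.

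The interaction asked whether the Pi response differed between the genotypes, and 2 probesets passed. AT4G38410 responded by 2.18 less in per1 on the log2 scale, an interaction of -2.18 ± 0.22 with an adjusted p from limma of 0.030. In per1 its signal was 600 ± 28.9 in control and 708 ± 86.9 in Pi-free medium. The interaction was -1.94 and -2.42 within replicate numbers 1 and 2. The unnamed probeset A had an interaction of -2.66 ± 0.20 with an adjusted p of 0.0029. Its signal rose from 131 ± 23.8 to 2190 ± 214 in Col-0, and in per1 stood at 659 ± 46.6 in control and 1590 ± 18.4 in Pi-free medium. The next named genes did not pass the test. AT3G43740 had an interaction of 1.27 ± 0.17 and BGLU25 one of -1.16 ± 0.16, both with an adjusted p of 0.18, and the endoglucanase gene GH9B13 had one of 1.02 ± 0.18 with an adjusted p of 0.65. The 4 measured of the 25 root hair genes fixed beforehand had a median interaction of -0.44 and 4 of 4 were below 0. Their list passed camera with an adjusted p of 0.013, and had an adjusted p of 0.55 with an estimated correlation. EXPA18 stood at -0.47 ± 0.15 and PRX44 at -0.54 ± 0.19; over all probesets 0 of the 4 were called, and adjusted over the list alone 2 fell. The count of probesets was 0 without either Pi-free per1 array, with 1009 and 863 at an unadjusted p under 0.05 in limma. It was 2 without the Pi-free Col-0 array of replicate 1 and 1 without any other array; over these 8 fits AT4G38410 passed in 1, probeset A in 6 and the root hair list in 4.

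Averaged over the genotypes, Pi withdrawal raised 22 probesets and lowered 7. Among named genes AT4G38410 rose by 1.32 ± 0.11, AT2G32190 by 0.91 ± 0.12, AT2G46600 by 0.69 ± 0.08 and AT5G19090 by 0.64 ± 0.09. Lower were PRX69 at -0.74 ± 0.10, with 1 of the 20 class III peroxidase genes called over all probesets, and AT4G30320 and AT2G37750, both at -0.63 ± 0.09. The adjusted p from limma was 0.0027 for AT4G38410, 0.026 for AT2G32190, 0.015 for AT2G46600, 0.037 for AT5G19090, 0.032 for AT4G30320 and 0.033 for PRX69 and AT2G37750. Adjusted over the list alone, 2 class III peroxidase genes rose and 6 fell, and the list as a whole did not pass camera, with an adjusted p of 0.75, a median of 0.11 and a mean of -0.02. The 14 other phosphate-responsive loci had a median of 0.29 and an adjusted p of 0.00016, or an adjusted p of 0.72 with an estimated correlation. The 69 plastid-encoded genes had a median of 0.16 and an adjusted p of 4.2e-05, or an adjusted p of 0.94 with an estimated correlation. The 3'/5' signal ratio of actin, a sign of RNA quality, was 4.07 to 5.49 in Pi-free and 4.98 to 6.38 in control medium. It was lower in Pi-free medium in each same-numbered pair of a genotype. The GAPDH ratio showed no such order, at 1.22 to 1.61 and 1.31 to 1.58. Whether RNA quality bears on the Pi responses was not tested. The count was 27 without the Pi-free Col-0 array of replicate 1, 2 without the Pi-free per1 array of replicate 2, and 6 to 10 without any other array. In those 8 fits AT4G38410 passed in 7, AT2G46600 in 1, and AT2G32190, AT5G19090, PRX69, AT4G30320 and AT2G37750 in 0.

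The mutant was compared with the wild type before any Pi withdrawal. In control medium AT1G09750, an aspartyl protease gene, was lower in per1 at -1.60 ± 0.17 on the log2 scale, with a signal of 262 ± 13.9 against 825 ± 10.8 in Col-0 (SD, n = 2). The differences were -1.53 and -1.66 within replicate numbers 1 and 2. AT2G41650 stood at -1.33 ± 0.16 and the serine carboxypeptidase-like gene scpl26 at -0.81 ± 0.10. BGLU46, a beta-glucosidase gene, was higher in per1 by 1.11 ± 0.14, with 530 ± 10.5 against 238 ± 24.7. The adjusted p from limma was 0.019 for AT1G09750, 0.026 for AT2G41650 and 0.032 for scpl26 and BGLU46. AT1G30760, a berberine-bridge-like oxidase gene, stood at 2.01 ± 0.30 and did not pass, with an adjusted p of 0.077, or 0.031 with the replicate number in the model. Counted over all probesets, 5 were higher and 8 lower. The count was 14 and 9 without either Pi-free Col-0 array and 1 to 3 without any other array, and AT1G09750 passed in 4 of those 8 fits, AT2G41650 in 2, and BGLU46 and scpl26 in 1. The 25S rRNA control probeset read 99.7 and 203.5 on the per1 arrays of replicates 1 and 2 and 47 and 117.2 on the Col-0 arrays.

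Several gene groups shifted in per1 in control medium. The 3 measured of the 17 green shoot tissue markers had a median of -0.77, with RCA, Rubisco activase, at -0.77 ± 0.19 and LHCB4.1, a light-harvesting protein gene, at -0.82 ± 0.21. The list passed camera with an adjusted p of 0.00071, and had an adjusted p of 0.21 with an estimated correlation. Adjusted over the list alone, 2 of the 3 fell, and 0 were called over all probesets. The 5 measured of the 25 proteasome subunit genes had a median of 0.28, led by RPN9A at 0.30 ± 0.10 and RPN11 at 0.31 ± 0.11. Their adjusted p was 0.029, or an adjusted p of 0.21 with an estimated correlation, and 0 members were called over all probesets or adjusted over the list alone. Among added lists, 37 cytosolic ribosomal protein genes had a median of 0.13, 33 of them higher, with an adjusted p of 0.0015, or an adjusted p of 0.66 with an estimated correlation. The 16 root hair extensins and further root hair genes had a median of -0.32, 13 of them lower, with an adjusted p of 0.0064, or an adjusted p of 0.66 with an estimated correlation. The xyloglucan endotransglucosylase gene XTH26 stood at -1.14 ± 0.37 and the extensin gene AT4G08410, measured by a probeset that can detect related transcripts, at -0.66 ± 0.14. The fixed root hair list had a median of 0.02, a mean of -0.01 and an adjusted p of 0.99. In the 8 fits without 1 array the green shoot list passed in 8, the longer root hair list and the ribosomal list in 7 and the proteasome list in 5.

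In Pi-free medium, per1 had less AT4G38410 transcript than Col-0, at -1.59 ± 0.16, and more BGLU46 transcript, at 1.28 ± 0.14. Their adjusted p from limma were 0.047 and 0.049, and these were the genes under the naming rule that passed. QQS, picked after its values were seen because its mean lay under the signal condition of that rule, also passed, at 2.91 with an adjusted p of 0.049. Named genes that did not pass included OSM34, an osmotin gene, at 1.07 ± 0.16 with an adjusted p of 0.086, AT1G09750 at -1.21 ± 0.17 with an adjusted p of 0.062, and EXPA18 at -0.71 ± 0.11 with an adjusted p of 0.087. With the replicate number in the model their adjusted p were 0.017, 0.029 and 0.041. EXPA18 had a signal of 817 ± 73.8 in per1 and 1340 ± 39.1 in Col-0. Counted over all probesets, 3 were higher and 4 lower. The 25S rRNA control probeset read 88.4 and 241.8 on the per1 arrays of replicates 1 and 2 and 51.8 and 143.4 on the Col-0 arrays. Leaving out any 1 of the 8 arrays left 0 calls in limma, with 1580 to 3620 probesets at an unadjusted p under 0.05.

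Root hair genes were lower in per1 in Pi-free medium as groups. The 4 measured of the 25 genes fixed beforehand had a median of -0.41, with EXPA18 as above, PRX44 at -0.52 ± 0.13 and EXPA7 at -0.30 ± 0.15. Camera gave an adjusted p of 0.0028, or an adjusted p of 0.23 with an estimated correlation, and 0 of the 4 were called over all probesets, while adjusted over the list alone 2 fell. The 16 root hair extensins and further root hair genes had a median of -0.54 with 15 of 16 lower; 0 of them were called over all probesets, and adjusted over the list alone 1 rose and 9 fell. AT4G08410 stood at -0.99 ± 0.14, with an adjusted p from limma of 0.071, or 0.0084 with the replicate number in the model, and XTH26 stood at -1.85 ± 0.37, with an adjusted p of 0.14. The list's adjusted p was 3.6e-07, or an adjusted p of 0.19 with an estimated correlation. The extensin gene AT1G26250 stood at 1.1 ± 0.24, with an adjusted p of 0.18. The 12 members outside the fixed list had a median of -0.60 and an unadjusted p of 2.1e-06. The 3 green shoot tissue markers had a median of -0.69, with an adjusted p of 0.0028, or an adjusted p of 0.23 with an estimated correlation, and 0 were called over all probesets, while adjusted over the list alone 2 fell. The 69 plastid-encoded genes had a median of 0.20, with an adjusted p of 7.1e-05, or an adjusted p of 0.62 with an estimated correlation.

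**Figure D2:**
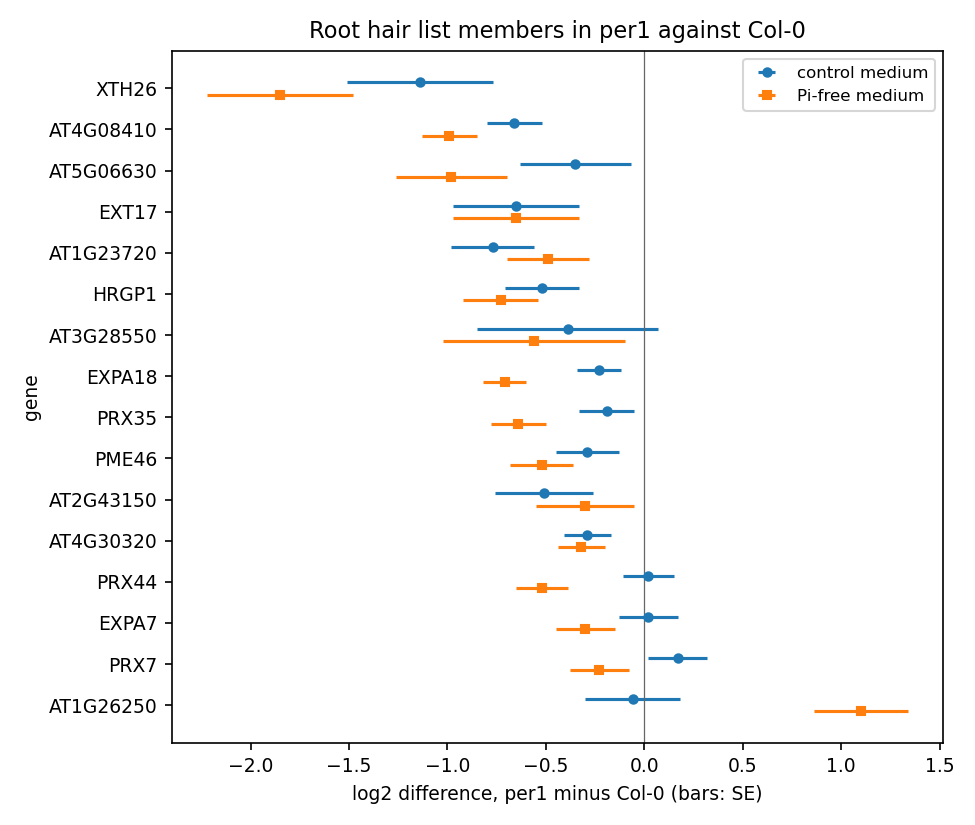
Log2 difference between per1 and Col-0 (x axis) for the 16 members of the list of root hair extensins and further root hair genes (y axis), in control medium (circles) and Pi-free medium (squares). Bars are SE from the moderated fit, with 2 arrays per group. In Pi-free medium 15 of the 16 members lie below 0, with AT1G26250 above it at 1.1.

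Averaged over the media, the genotype difference covered the most probesets, 73 higher and 113 lower in per1, of which 92 had a single named gene. AT4G33720, a pathogenesis-related CAP family gene, was higher by 1.59 ± 0.20, AT1G30760 by 1.42 ± 0.21, AT5G53010 by 1.42 ± 0.20, BGLU46 by 1.20 ± 0.10 and AT5G12420, a wax ester synthase-like gene, by 1.08 ± 0.13. Lower were AT4G12500 at -1.54 ± 0.22, AT1G09750 at -1.41 ± 0.12, AT1G05340 at -1.25 ± 0.23, AT5G48430 at -1.15 ± 0.15 and AT2G41650 at -1.13 ± 0.11. Their adjusted p from limma ran from 0.0020 for BGLU46 and AT1G09750 to 0.044 for AT1G05340. Within replicate numbers 1 and 2, BGLU46 differed by 1.24 and 1.15, and AT1G09750 by -1.55 and -1.27. The numbers lay further apart for AT5G12420, at 1.4 and 0.75, and for AT5G48430, at -0.77 and -1.52. Limma without the intensity trend gave 0 calls for this comparison, with an adjusted p of 0.06 for BGLU46 and AT1G09750 and 0.088 for AT2G41650. The count was 232 without the Pi-free Col-0 array of replicate 1 and 12 to 66 without any other array, lowest without the Pi-free per1 array of replicate 1. BGLU46, AT1G09750 and AT2G41650 passed in 8 of those 8 fits, AT5G12420 in 5, AT4G33720 and AT4G12500 in 4, AT1G30760 and AT5G48430 in 3, AT5G53010 in 2 and AT1G05340 in 1.

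Groups with a genotype difference over both media included the 16 root hair extensins and further root hair genes, with a median of -0.44 and 3 members called as lower over all probesets: AT4G08410 at -0.82 ± 0.10, EXPA18 at -0.47 ± 0.08 and XTH26 at -1.50 ± 0.27. The list had an adjusted p of 1.3e-06, or an adjusted p of 0.22 with an estimated correlation. The 4 measured of the 25 root hair genes fixed beforehand did not pass as a list, with a median of -0.20 and an adjusted p of 0.067, or an adjusted p of 0.41 with an estimated correlation, and 1 of them, EXPA18, was called. The green shoot tissue markers moved in the same direction, with a median of -0.73 and an adjusted p of 0.00023, or an adjusted p of 0.28 with an estimated correlation. RCA was called as lower at -0.73 ± 0.13, 1 of the 3 over all probesets, and adjusted over the list alone 3 fell. Among 20 class III peroxidase genes, PRX59 was called as higher at 0.91 ± 0.15, and adjusted over the list alone 2 rose and 1 fell. The list had an adjusted p of 0.44. Among the 14 other phosphate-responsive loci, the purple acid phosphatase gene PAP1 (AT1G13750) was called as lower at -0.62 ± 0.10. The list had an adjusted p of 0.088. The 37 ribosomal protein genes had a median of 0.10 and an adjusted p of 0.00043, or an adjusted p of 0.59 with an estimated correlation. The 69 plastid-encoded genes had a median of 0.14 and an adjusted p of 0.00012, and 23 cytochrome P450 genes a median of -0.27 and an adjusted p of 0.048. With an estimated correlation the adjusted p was 0.59 for both. Without 1 array the cytochrome P450 list passed in 3 of 8 fits and the plastid list in 7. With the replicate number in the model the cytochrome P450 list did not pass, with an adjusted p of 0.054. The 5 proteasome subunit genes had a median of 0.20 and an adjusted p of 0.067, or adjusted p of 0.28 with an estimated correlation and 0.018 with fry. The lists of 6 auxin genes, 3 reference genes, 4 iron deficiency genes and 4 phosphate transport genes had adjusted p of 0.43, 0.94, 0.99 and 0.94. The phosphate transport list had a median of 0.01 and a mean of -0.08, and the iron deficiency list had a median of -0.06 while its test pointed up.

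**Figure D3:**
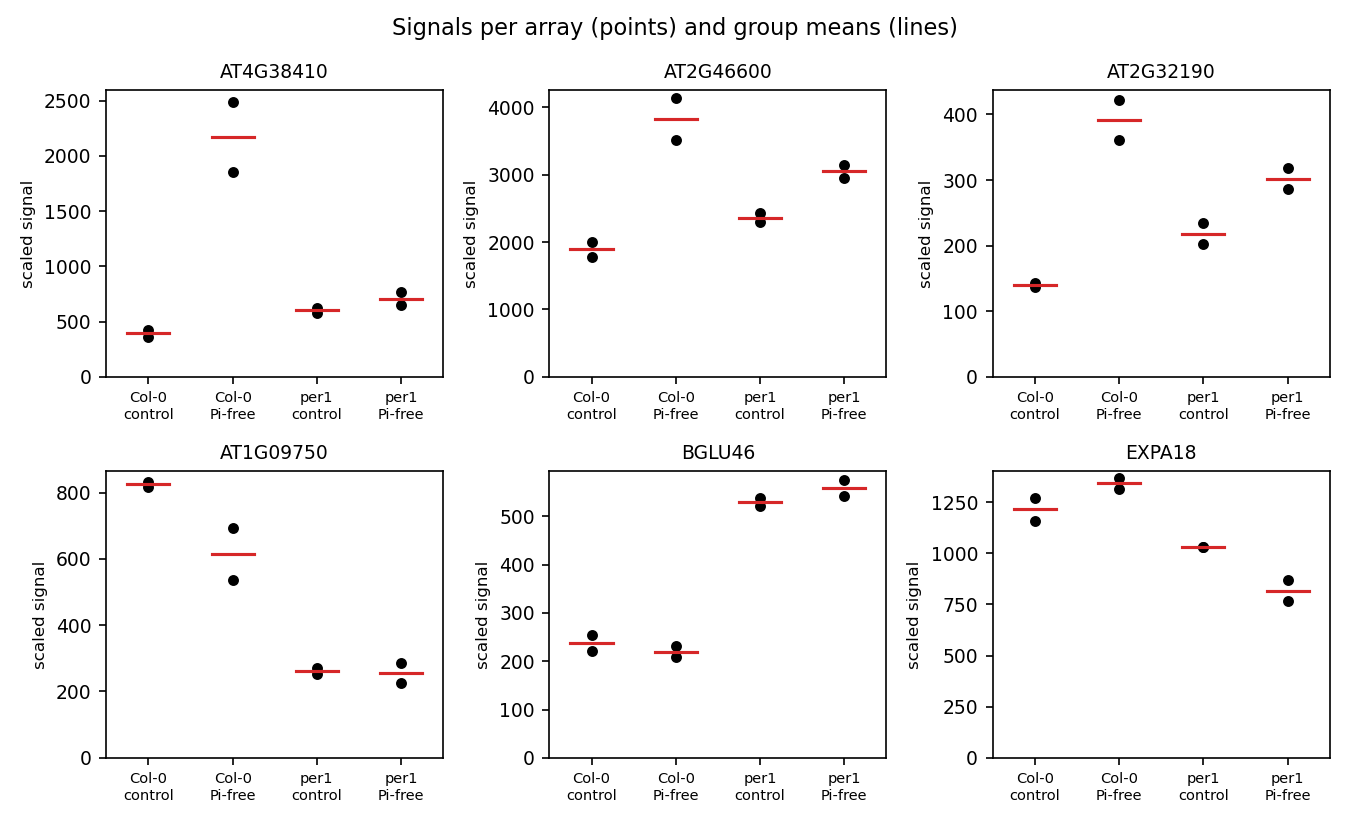
Scaled signal on each array (points) and group mean (lines) for 6 genes, with the 4 groups on the x axis and signal on a linear y axis from 0. AT4G38410 has a mean of 2170 in Pi-free Col-0 and 708 in Pi-free per1, and the BGLU46 arrays of per1 lie above those of Col-0 in both media.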

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

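The tests of held-out arrays, of the spread between arrays, of probeset type, of replicate numbers and of the share of root hair cells were chosen after the results they bear on were seen. The test without the Pi-free Col-0 array of replicate 2 was set before its result was seen.

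AT4G38410 and the unnamed probeset A stood out because their Pi responses differed between the genotypes, by -2.18 and -2.66 on the log2 scale, per1 minus Col-0. The fixed root hair list stood out for the same reason, with an adjusted p of 0.013 for its interaction, or an adjusted p of 0.55 with an estimated correlation. It passed in 4 of 8 fits without 1 array, and its adjusted p over all alternatives ran from 0.0028 to 0.55.

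Fewer probesets passed for the Pi response in per1 than in Col-0, 1 against 14, and 14 of the 14 Col-0 calls changed more in Col-0 than in per1, although calls picked in Col-0 favour Col-0. In per1, 13 of the 14 changed in the same direction as in Col-0. Their median absolute change was 1.37 in Col-0, and their median signed change in per1 was 0.54. Noisier per1 arrays were not tested by the median within-group SD, which in per1 minus that in Col-0 was -0.02, since the fit holds 1 variance per probeset for both genotypes, and the SDs were 0.136 in Col-0 and 0.148 in per1 in control medium and 0.178 and 0.125 in Pi-free medium. Regression to the mean stays open: among the 50 probesets with the largest change in 1 Col-0 pair, the held-out Col-0 median was 0.68 against per1 medians of 0.26 and 0.47 in the first selection and 0.58 against 0.29 and 0.38 in the other, with a gap to the larger per1 median, from unrounded medians, of 0.21 in the closer case and a gap above the difference between the per1 medians in only 1 selection; probesets picked in 1 per1 pair had held-out per1 medians of 0.52 and 0.20, against Col-0 medians of 0.43 and 0.62 and of 0.38 and 0.16. An outlying array stays open too, since the Col-0 count was 3 without the Pi-free Col-0 array of replicate 2, but 3 to 4 without any 1 array. A smaller response in per1 may be biological and remains an untested hypothesis, with AT4G38410 and probeset A as the 2 probesets that passed the test of the difference. For probeset A the difference lay largely in control medium, where per1 was higher by 2.21 ± 0.14. In Pi-free medium its signal was 2190 ± 214 in Col-0 and 1590 ± 18.4 in per1.

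The 16 root hair extensins and further root hair genes had a median of -0.44 in per1 over both media, with 3 members called and an adjusted p of 1.3e-06, or an adjusted p of 0.22 with an estimated correlation, while the 4 root hair genes fixed beforehand did not pass, with a median of -0.20 and an adjusted p of 0.067, or 0.41 with an estimated correlation, and the 3 green shoot tissue markers were lower too, with a median of -0.73 and an adjusted p of 0.28 with an estimated correlation. Probesets with identifiers ending in _s_at or _x_at do not alone account for the lower median of the 16. The 12 members with other probesets had a median of -0.41 over both media. Whether those other probesets detect related transcripts was not tested. A lower share of root hair cells stays open. In control medium the 4 genes fixed beforehand had a median of 0.02 and the other 12 one of -0.45. An exact permutation of the genes, counting both tails, gave a p of 0.0082 over 1820 groupings. That test treats genes as independent replicates, although the estimated correlation within the 4 genes was 0.23. The 4 are also only those of 25 listed genes that had a named probeset. The 4 thus did not share the lower median of the other 12, which does not settle the share of cells. In Pi-free medium the medians were -0.41 and -0.60 and the exact permutation p was 0.59. Fewer root hair cells and lower expression per cell cannot be told apart in either medium. The spiked controls differed by replicate number. Each number holds 1 array of every group, so by design a shift common to all arrays of a number cancels from the genotype difference. The medians within the numbers were -0.43 and -0.55. They show the lower median in both numbers but are no separate test of a batch. On the arrays numbered 1 the 5' BioD probeset read 1562.4 and 1624.2 in Col-0 and 1599.6 and 1655.5 in per1. The 3' one read 2556.1 and 2606.1 in Col-0 and 2723.5 and 2710.5 in per1. On those numbered 2 the genotypes overlapped for both. The 25S rRNA signal, not a spiked control, was higher on the per1 arrays of each number. A batch along genotype, as in sample preparation, and the genotype itself cannot be told apart.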

How the results depend on the processing

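Alternatives were run for 80 gene results and 21 list results, and none of these changed direction; other named genes and lists were not rerun singly. Of 358 list results under alternatives 290 stayed on their side of the threshold and 68 lost their call. The list tests do not use limma's variance settings. The 21 list results without the trend and the 21 with robust variances therefore repeat the main ones and could not move. Of 1200 named-gene results 928 stayed, 61 gained a call and 211 lost it. Many of the 80 gene results were not called in the main fit, so the 928 include results that stayed uncalled. Only called results could lose a call. Counts of calls moved more, in the order Col-0 response, per1 response, genotype in control medium, genotype in Pi-free medium, interaction, averaged response and averaged genotype difference, whose counts were 14, 1, 13, 7, 2, 29 and 186. A filter at the 40th percentile, which tests fewer probesets, gave 42, 6, 73 and 74 for the first 4, and 65 and 477 for the averaged ones. A pseudocount of 1 gave 26, 2, 20 and 16 for the first 4, and one of 64 gave 2 in Pi-free medium and 1 for the interaction. Quantile normalization gave 1 for the interaction. The replicate block, set beforehand as an alternative, gave 31, 4, 42 and 48, and 49 and 357 for the averaged comparisons. Over all probesets, residuals of same-numbered arrays correlated by 0.00205 to 0.0771. These low values do not rule out an effect of the replicate number on part of the probesets. The higher counts with the block leave such an effect open. Limma without the intensity trend gave 1, 0, 0, 0, 0, 2 and 0, and with robust variances 29, 5, 22 and 17 for the first 4. Fits of only the groups compared gave 3, 0, 0 and 0, with fewer arrays. Over the 19 limma fits with 0 calls, 794 to 3620 probesets had an unadjusted p under 0.05. At adjusted p under 0.1 the counts were 33, 6, 35 and 22, and 50 and 491 for the averaged comparisons; under 0.01 they were 3, 1, 1, 0, 1, 9 and 36. Without 1 array, where the lone array is assumed to vary like the other groups, they were 3 to 4, 0 to 2, 1 to 14, 0 to 0, 0 to 2, 2 to 27 and 12 to 232. List calls, 21 in all, numbered 0 with an estimated correlation, 7 with fry, 6 of them among the 21, and 19 to 21 without 1 array, where 145 of the earlier calls stayed and 23 were lost over the 8 fits. Fry called the green shoot markers in control medium, in Pi-free medium and averaged over media, with adjusted p of 0.02, 0.038 and 0.015. It called the proteasome list in control medium (0.02) and averaged over media (0.018). It also called the fixed root hair list in Pi-free medium (0.038) and the longer one averaged over media (0.041). The other list calls did not pass fry, with 0.1 for the fixed root hair list in per1 and 0.21 for its interaction. A further alternative, chosen after seeing the data, left out the 4 shared root hair genes: 3 of the 4 calls of the larger list stayed under an unadjusted p of 0.05, and the per1 response gave 0.27. The cause of these shifts was not tested beyond the fewer probesets or arrays named. Signals near the unspiked controls limit what low probesets can show.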

Other observations

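The tests of the chromosome positions and of per1 in control medium were chosen after related results were seen; those of the iron wording and of other splits of the arrays were set before.

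Across the 11373 probesets with a mean above the median, the Pi responses of Col-0 and per1 had a Pearson r of 0.147 and a Spearman rho of 0.0307. The genotype differences in the 2 media, which share no array, had an r of 0.442 and a rho of 0.366. Over all 22746 probesets the r was 0.042 for the Pi responses and 0.196 for the genotype differences. These correlations run across genes, which are not independent replicates. Of the serine carboxypeptidase-like genes, scpl26 was lower in per1 over both media at -0.75 ± 0.07 and SCPL27 at -0.68 ± 0.10, with adjusted p from limma of 0.0035 and 0.019, while the 29 genes as a list had an adjusted p of 0.14.

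Chance division of the 8 arrays was tested for the averaged comparisons in a model with 1 term for each factor, leaving out the split by the other factor. The genotype split gave 233 probesets and the highest of the other splits 0, so 1 of 34 splits gave as many. The medium split gave 20 and the highest of the others 1, again 1 of 34 splits. Chance division is argued against for both but not excluded, since 1 of 34 is the smallest share that this test can give.

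The descriptions of 3 arrays mention iron deficiency and those of 5 mention iron efficiency, across groups that the other labels separate by Pi. A term for this wording beside the 4 group means called 0 probesets in limma, with 1157 at an unadjusted p under 0.05 where 1137 were expected by chance. A difference in iron status between arrays of a group was set beforehand to need 10 or more calls, which was not met. The Pi response in per1, with 1 call, and the interaction, with 2, also lay under that bar. The 0 calls therefore do not rule out a difference in iron status.

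Of the 92 named loci with a genotype difference over both media, 24 lay on chromosome 4, where 13.5 were expected from the named loci, with a Fisher exact p of 0.0043 and an adjusted p of 0.021 over 5 chromosomes. A segment carried from another background may lie behind this, but not one linked to UBP14, whose locus identifier places it on chromosome 3, where 11 calls stood against 18.9 expected (Fisher exact p 0.038, adjusted p 0.096). The densest window of 100 named loci, neighbours in the order of their identifiers, held 4 calls, the median of 1000 random placements, with a permutation p of 0.90. The excess on chromosome 4 keeps a segment not linked to UBP14 open.

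Whether per1 in control medium already sat nearer to the Pi-deficient state could not be settled. With the Col-0 control arrays split, so that one defined the 50 largest Pi responses and the other served as the baseline, the median shift of per1 along them was 0.01 in one split and 0.23 in the other. The unnamed probeset A was higher in per1 in control medium by 2.21 ± 0.14, with an adjusted p from limma of 0.00067. In the same comparison probeset B stood at 0.08 ± 0.16, with an adjusted p of 0.93, and AT4G38410 at 0.60 ± 0.16, with an adjusted p of 0.27.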
